A study of Homo sapiens with 54 samples.

How the data were processed

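Messenger RNA levels were measured in 54 human tissue samples, each on its own Affymetrix oligonucleotide array. Of these, 39 samples were soft tissue sarcomas of 8 labelled types and 15 were normal tissues, 1 from each of 15 organs. Groups and sample names were taken from the labels. Where the labels gave no replicate number, samples were numbered in the order of the series, so that a number only names a sample. The labels name no donors, batches or protocols. The p-values below therefore measure the spread between these samples and, among the normal tissues, mostly the spread between organs. The number of arrays limits the precision of every value.

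The authors deposited 1 intensity value per probe set and array on a linear scale. Leaving out the lowest and highest 2 percent of the probe sets, the mean deposited intensity was between 500.1 and 500.3 on every array, so the arrays had been scaled to a common trimmed mean. The program that made these values is not given in the sources used here. The median intensity per array ran from 141.4 to 279.2. Values were transformed as log2(value + 16). The pseudocount keeps low intensities from dominating and understates the change of dim genes. The medians of the log2 values differed between arrays by 0.91, more than the limit of 0.5 fixed beforehand, so the arrays were quantile normalized. No pair of arrays held the same values, and the closest pair had a Pearson correlation of 0.916 across probe sets, which are not independent replicates.

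The table held 22283 probe sets, 68 of them controls. The platform annotation gave 1 gene symbol for 19065 probe sets, several symbols for 1043 and none here for 2107; probe sets with several or no symbols were not named. No symbol had to be updated, and 12 probe sets kept the annotation's symbol because no current entry was found. Each of 11939 genes was represented by its probe set with the highest mean over all arrays, and 4304 of them had more than 1 probe set. The 31 probe sets of sex-linked genes that could reveal a donor's sex were removed before any fit. A gene was tested when its representative reached the median of its array in at least 3 of the arrays fitted.

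Genes were tested with limma (version 3.58.1, in R 4.3.3), using lmFit and eBayes with an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05 with at least a 2-fold change. The sarcomas were compared with the normal tissues over all 54 arrays. Each sarcoma type was compared with the mean of the other 7 type means in a fit of the 39 sarcomas, where all types share 1 estimate of spread. All adjusted p-values of genes come from these limma fits. Gene lists were tested with camera in limma, with a preset inter-gene correlation of 0.01, over 29 lists fixed before the data were examined and with at least 5 members tested. The tests were repeated with an estimated correlation and with fry, which asks whether the members of a list moved together in 1 direction. The designs, most alternatives and the gene lists were fixed before the data were examined. So was the rule for naming genes. For sarcomas against normal tissues it takes the 12 called genes with the largest rise and the 12 with the largest fall. For each type it takes the 5 with the largest rise and the 3 with the largest fall. Added to these are 2 to 4 members of each list described, those with the largest changes, and 12 genes fixed by type whatever their result. The similarity of arrays within a type was tested by permuting the type labels 100000 times, and the ratio of 3' to 5' control probe sets by a permutation test of 100000 resamples, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The plots were drawn with matplotlib 3.10.9.

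The tests were tried on simulated data with 200 changed genes, drawn with independent genes and 1 spread per gene for all arrays. Organs that differ, correlated genes and arrays that stand apart were not simulated, so the shares called may not hold for the real data. For sarcomas against normal tissues, among 10147 genes, 83.5% of genes changed by 1.5 on the log2 scale were called, and 99.5% of those changed by 3. Among the 9411 genes of the type comparisons, the share of genes changed by 2 on the log2 scale that were called was 97% for MFH and 95.5% for fibrosarcoma. It was 62.5% for GIST and 77% for lipo pleo, the types with the fewest samples.

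The alternatives changed the pseudocount, the normalization, the filter, the choice of probe set, the weights of arrays and types, the thresholds, the samples in the fit and the list test, and left out single samples. Each normal tissue was left out in turn against normal tissue, and each sample of a type in the comparison of that type. The replicate number as a block was among the alternatives, although it pairs no samples. Covariates for RNA quality and for the CreX hybridisation control, the use of only 5 normal tissues with little epithelium, and fits without the arrays that stood apart were chosen after seeing the data. Single types were not tested against normal tissue gene by gene, and neither clinical data nor genome coordinates were used here. The 12q13-15 list was fixed from general knowledge of that region.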

Results

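Expression was profiled in 39 soft tissue sarcomas and 15 normal tissues. The sarcomas were 9 samples labelled MFH, 7 fibrosarcomas, 6 leiomyosarcomas, 4 synovial sarcomas, 4 labelled lipo dediff, 4 labelled round cell, 3 labelled lipo pleo and 2 gastrointestinal stromal tumors (GIST). The labels do not spell out the names MFH, lipo dediff, lipo pleo and round cell, and these are used as given. The normal tissues were brain, stomach, colon, pancreas, prostate, skin, small intestine, adrenal, connective tissue, heart, kidney, liver, lung, skeletal muscle and spleen. As a check of the labels, 33 of 39 tissue markers fixed beforehand were highest on the array of their own organ. Among the exceptions, the small intestine markers SI, APOA4 and FABP2 ranked 2, 3 and 8 of the 15 normal tissues on their own array. The colon marker CA1 ranked 15 on the array labelled colon. The array labelled colon also had high levels of small intestine genes, such as the sucrase SI at 13.3. Levels are log2 values after quantile normalization, and fold changes are differences of these levels with their standard errors (SE). A list effect is the mean log2 fold change of the members of a gene list minus that of all other genes tested.

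The first comparison asked what separates sarcoma from normal tissue. Genes of cell division were higher in the sarcomas. TOP2A, the topoisomerase that untangles replicated DNA, was higher by 3.59 ± 0.35 (SE), and 36 of 39 sarcomas lay above every normal tissue. The spindle genes ASPM (3.56 ± 0.40), KIF20A (3.29 ± 0.33), TPX2 (2.97 ± 0.36) and SPDL1 (2.90 ± 0.32), the mitotic kinase PBK (3.03 ± 0.31) and FOXM1 (2.96 ± 0.36), a transcription factor of dividing cells, were among the 12 largest rises. Of these, PBK and TPX2 exceeded every normal tissue in 36 sarcomas and ASPM in 32. The other large rises were genes of the connective tissue matrix. SERPINH1, a collagen chaperone, rose by 3.72 ± 0.43, the metalloprotease ADAM12 by 3.25 ± 0.47, the proteoglycan VCAN by 3.17 ± 0.38, the collagen COL5A2 by 3.09 ± 0.41 and the microfibril gene MFAP2 by 2.91 ± 0.38. SERPINH1 exceeded every normal tissue in only 15 sarcomas and ADAM12 in 10. All 12 genes had an adjusted p of 2.53e-07 or lower.

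The gene lists showed the same groups. Of 32 tested members of the mitosis and cell division list, 30 were called higher, and the list effect was 2.15 (adjusted p = 2.37e-29). Of 26 DNA replication genes, 18 rose, with TYMS at 2.89, GINS1 at 2.48 and MCM6 at 2.11, for a list effect of 1.38 (adjusted p = 1.44e-16). Of 14 DNA repair genes, 8 rose, with FANCI at 2.57, BARD1 at 2.49 and RAD51AP1 at 2.19, for a list effect of 1.15 (adjusted p = 1.66e-07). These 3 lists also passed the threshold with an estimated correlation, with adjusted p = 0.0373, 0.0306 and 0.0306. Of 23 collagen and matrix genes, 17 rose, POSTN by 2.86 and COL1A1 by 2.84 among them, and the list effect was 1.74 (adjusted p = 1.91e-09). Its call was lost at adjusted p = 0.171 with an estimated correlation. Of 24 matrix remodelling enzymes and their partners, 12 rose, among them LOXL2 at 2.53 and FAP at 2.43, for a list effect of 1.28 (adjusted p = 3.68e-06). This call too was lost, at adjusted p = 0.227 with an estimated correlation. Adjusted over the list alone, the numbers called in these 5 lists were the same. Against only the 8 normal tissues rich in mesenchyme or muscle, the matrix list was at 1.00, COL1A1 at 1.78, and POSTN (1.89) and FAP (1.88) were no longer called. The collagen and matrix score, the mean level of the list's members, was 13.47 on the normal connective tissue array. The highest type mean was 12.86, in lipo dediff, and only lipo dediff 4 (13.59) lay above that array. The rise of this list is therefore over the mean of the normal organs and was not seen over connective tissue, a single array.

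Epithelial genes, and single genes of other mature tissues, were lower in the sarcomas. AZGP1, a secreted protein of glandular epithelium, fell by 3.98 on the log2 scale (SE 0.44) and lay below every normal tissue in 34 sarcomas. CDH1, the epithelial cadherin, was at -3.73 ± 0.66, the desmosome gene DSP at -3.30 ± 0.41 and the iron-binding secretory protein LTF at -3.30 ± 0.44. Of 17 epithelial markers, 16 were called lower, KRT18 at -3.16 and EPCAM at -3.08 among them, for a list effect of -2.18 (adjusted p = 8.54e-12). It held at adjusted p = 0.0373 with an estimated correlation. Other large falls were those of the chemokine CXCL14 (-3.72 ± 0.68), the prostaglandin synthase PTGDS (-3.62 ± 0.60), the smooth muscle myosin MYH11 (-3.53 ± 0.92), the alcohol dehydrogenase ADH1B (-3.46 ± 0.55), the chemokine receptor ACKR1 of venules and red blood cells (-3.22 ± 0.55), beta-globin HBB (-3.20 ± 0.40), the kinase PRKCZ (-3.20 ± 0.53) and the amine oxidase MAOA (-3.19 ± 0.50). The largest adjusted p among the 12 was 0.00197, for MYH11. Leiomyosarcoma did not share the fall of MYH11, which averaged 14.89 there and 11.63 in the normal tissues, a difference that was not tested. The epithelial fall depended on which normal tissues stood for comparison. Against only the 5 normal tissues with little epithelium, chosen after seeing the data, the epithelial list was at -0.61 (adjusted p = 0.256, from 1.74e-15 to 0.256 over its alternatives), and CDH1 (-0.55), MYH11 (-2.39), MAOA (-1.68) and KRT18 (-1.19) were no longer called. DSP was at -1.54 and ADH1B at -2.27 there and stayed called.

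**Figure D1:**
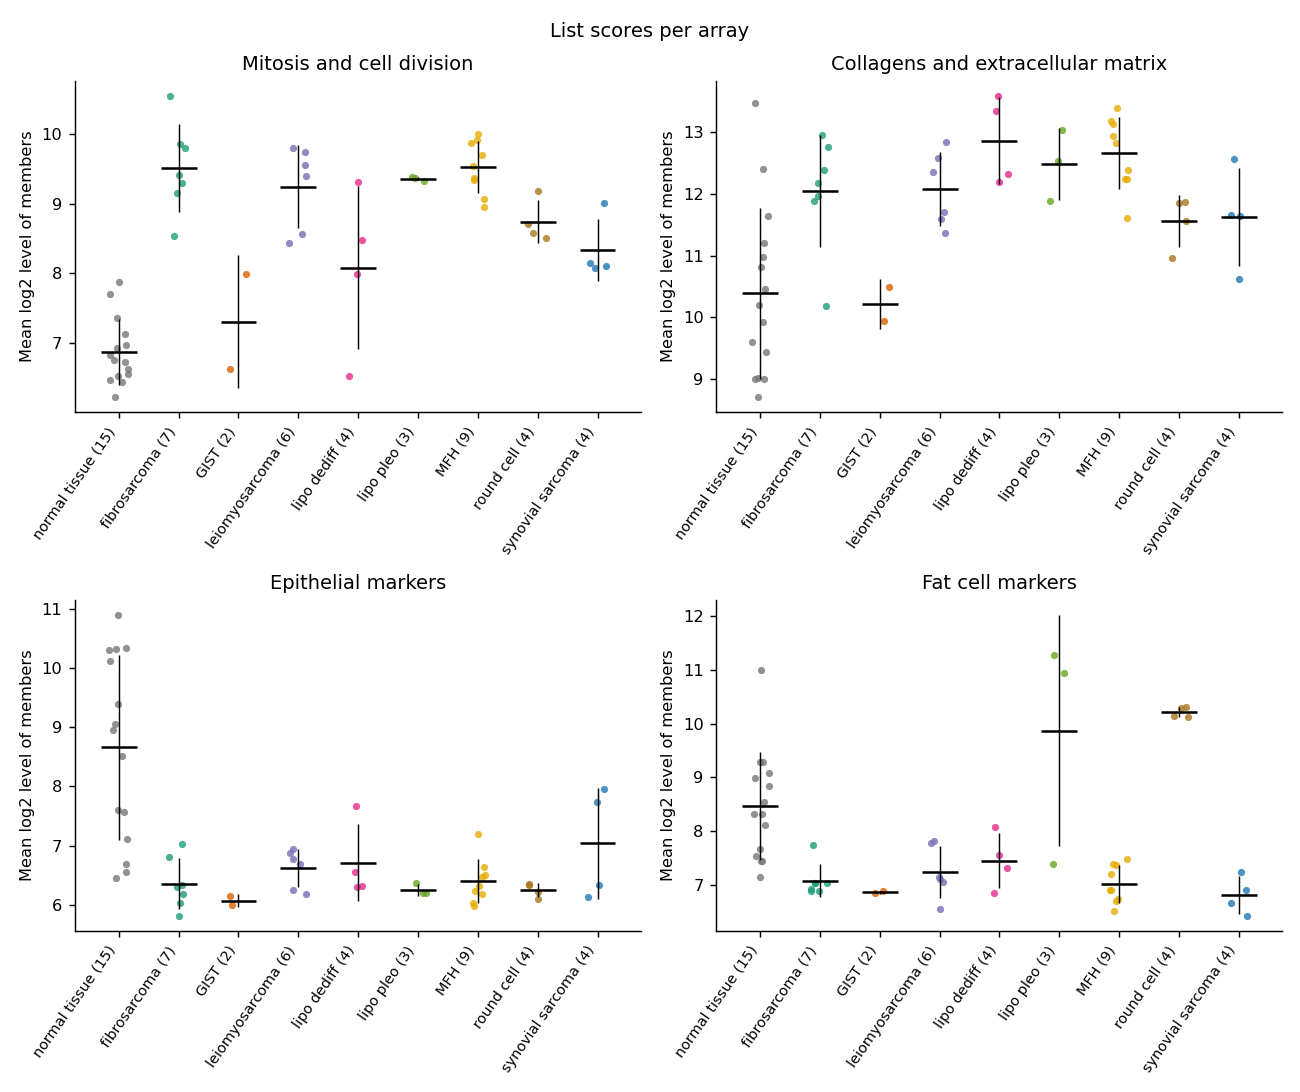
Mean log2 level of the members of 4 gene lists on each array (points), by group with the number of arrays, with the group mean (horizontal bar) and 1 SD on each side (vertical line). Mitosis scores averaged 6.87 in normal tissue and 9.53 in MFH, and the 4 round cell samples averaged 10.21 on the fat cell list against 8.47 in normal tissue.

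Some lists for other mature tissues were lower as well, more weakly. The red blood cell list had an effect of -1.32 (adjusted p = 0.00476), with HBB the only 1 of 5 members called, and stood at adjusted p = 0.0542 with an estimated correlation. The skeletal muscle list was at -1.05 with 5 of 16 members called lower, CKM at -2.06 and TNNC2 at -1.58 among them (adjusted p = 0.00705, and adjusted p = 0.713 with an estimated correlation). Without the skeletal muscle sample it was at -0.57 and not past the threshold (adjusted p = 0.113, from 9.09e-09 to 0.713 over its alternatives). CKM was not called without the heart (-1.53) or the skeletal muscle sample (-1.51), nor TNNC2 without the connective tissue (-1.31) or the skeletal muscle sample (-1.05). The lymphocyte list was at -0.71 with 4 of 19 members called lower, among them CD79A at -1.97 and CCR7 at -1.56, and the fat cell list at -0.85 with 3 of 15, among them PCK1 at -2.58 and GPD1 at -2.11. Their adjusted p were 0.00705 and 0.0342, and both had adjusted p = 0.713 with an estimated correlation. The fat cell call was also lost without the skin sample (-0.80, adjusted p = 0.0518) or the connective tissue sample (-0.68, adjusted p = 0.0901), within a range of 0.00142 to 0.713 over its alternatives. Adjusted over the list alone, the counts of these lists and of the epithelial list did not change.

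The other 19 lists did not pass the threshold with camera and the preset correlation. The macrophage list was at 0.77 (adjusted p = 0.0625, 2 of 14 called higher), neuron and glia at -0.58 (0.0520, 5 of 16 lower), oxidative phosphorylation at -0.28 (0.0598, none of 23), and protein folding and secretion at 0.40 (0.0722, 5 of 19 higher). The pluripotency and cancer-testis genes were at 0.96 (0.143) and the smooth muscle markers at -0.90 (0.202). The 13 remaining lists ran from -0.36 for the immediate early genes to 0.40 for the interferon response, with adjusted p from 0.202 to 0.885. Between these lay p53 targets, hypoxia and glycolysis, receptor tyrosine kinases, embryonic muscle, genes of the 12q13-15 amplicon, markers of GIST, synovial sarcoma, the Ewing family and myxoid liposarcoma, class II antigen presentation and endothelium. For the synovial sarcoma list the mean and the median of the members differed in sign (0.01 and -0.07). Adjusted over the list alone, the counts of 4 of these lists changed: interferon response from 3 higher to 2, immediate early genes from 2 lower to 1, GIST markers from 1 higher to 0, and neuron and glia from 0 higher to 1. With fry, the neuron and glia list (adjusted p = 0.011) and the receptor tyrosine kinases (0.012) did pass the threshold. So did the pluripotency and cancer-testis genes (0.024) and protein folding and secretion (0.026).

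In all, 768 genes were called higher and 727 lower in the sarcomas among 10147 genes tested. For 590 of the former and 573 of the latter, all 8 type means lay on the same side of the normal mean, and 73 genes exceeded every normal tissue in at least 30 sarcomas. Of the 24 genes named by size, 21 were called under every alternative that tested them, apart from the stricter limit of 0.01 on the adjusted p. The exceptions are CDH1, MYH11 and MAOA. Some genes were dropped by a filter and so not tested in every alternative, such as AZGP1, with 40 alternatives where TOP2A had 42. Averaging all probe sets of a gene in place of the brightest gave smaller changes for several, such as ADAM12 (1.51), TYMS (1.54), POSTN (1.52), LOXL2 (1.42), CDH1 (-2.31) and MYH11 (-2.15), all still called. The rise of the mitosis list differed between sarcoma types, from 0.43 in GIST to 2.66 in MFH (permutation test, adjusted p = 0.0015 over 10 lists). The log2 ratio of 3' to 5' control probe sets, a sign of RNA quality, was 0.45 ± 0.40 (SD, n = 39) in the sarcomas and 0.61 ± 0.43 (SD, n = 15) in the normal tissues. The difference of -0.15 did not exceed chance (p = 0.220, 2-sided permutation test).

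The second set of comparisons asked how the 8 sarcoma types differ from each other. Over the 2000 most variable genes, arrays of the same type had a mean Pearson correlation of 0.667, and arrays of different types 0.507. The difference of 0.16 was larger than in any of 100000 permutations of the type labels (1-sided permutation p = 1e-05, the smallest they can give). These correlations are across genes, which are not independent replicates. The nearest array was of the same type for 29 of 39 sarcomas. It was so for all leiomyosarcoma, round cell, synovial sarcoma and GIST samples, for 7 of 9 MFH and 5 of 7 fibrosarcoma samples, for 1 of 3 lipo pleo samples and for 0 of 4 lipo dediff samples. The mean correlation within a type was lowest in fibrosarcoma (0.54, against 0.50 to other types). Lipo dediff came next (0.58, against 0.54). Of 216 list tests in the type comparisons, 83 passed the threshold, and 6 of these also with an estimated correlation. For 88 of the 93 list results past the threshold in the whole study, the estimated correlation gave the highest adjusted p of all alternatives.

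**Figure D2:**
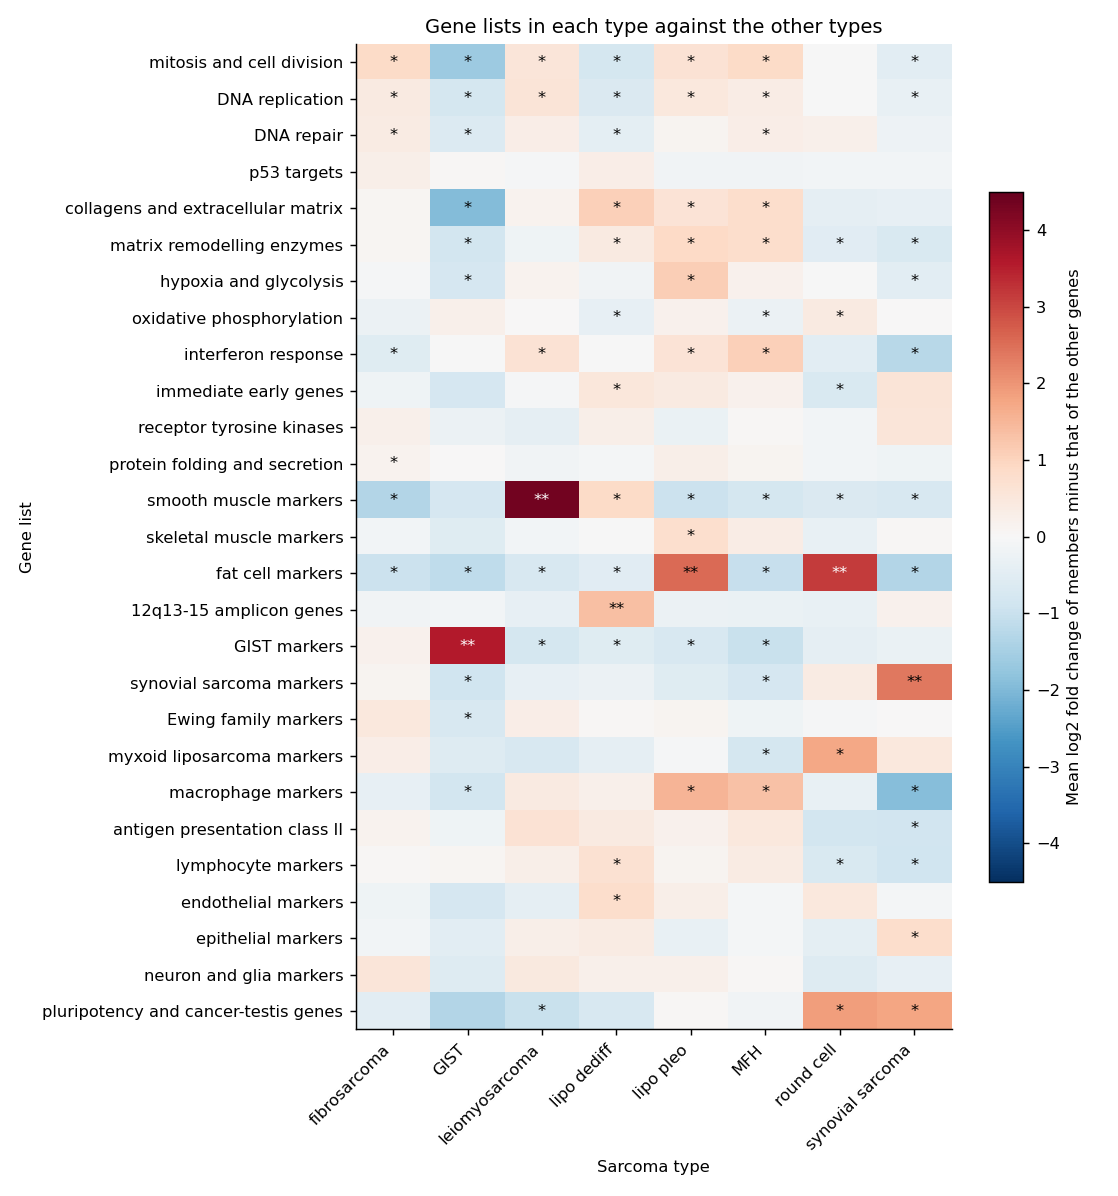
List effects (colour, log2, mean of the members minus that of the other genes) for 27 gene lists in each of 8 sarcoma types against the other types. A star marks an adjusted p under 0.05 with the preset correlation and a double star also with an estimated correlation, as for the smooth muscle list in leiomyosarcoma (4.35) and the fat cell list in round cell (3.13).

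The GIST samples had high levels of GIST marker genes. The receptor tyrosine kinase KIT was higher by 6.49 ± 0.73 (adjusted p = 1.54e-07), and both GIST arrays lay above all other sarcomas. GPR20, an orphan receptor, was higher by 7.51 ± 0.69, the carbonic anhydrase CA2 by 7.00 ± 0.67, the enkephalin precursor PENK by 6.89 ± 1.07, the chloride channel ANO1 by 6.76 ± 0.76 and the potassium channel KCNK3 by 6.71 ± 0.69. Of 14 GIST markers fixed beforehand, 9 were called higher, and 12 when adjusted over the list alone, with a list effect of 3.59 (adjusted p = 6.40e-19, and adjusted p = 8.09e-05 with an estimated correlation). Matrix genes were lower. COL6A3 was at -5.30 ± 0.73, the collagen processing enhancer PCOLCE at -4.72 ± 0.77 and the dystrophin partner SSPN at -4.39 ± 0.66. The matrix list was at -1.93 with 7 of 23 members lower, or 12 adjusted over the list alone (adjusted p = 1.39e-09, but adjusted p = 0.193 with an estimated correlation). Of 32 mitosis genes, 15 were called lower, or 22 adjusted over the list alone, CDC20 and TPX2 at -3.18 among them, for a list effect of -1.63 (adjusted p = 2.70e-17, but adjusted p = 0.329 with an estimated correlation). In all, 241 genes were called higher and 175 lower, which is 57.9% higher. With the scaling as deposited the share was 46.5% (249 and 287), where the median of all genes shifted to -0.11. With 2 samples the fit relies on the spread of the other types, and 133 genes were called without GIST 1 and 131 without GIST 2, the remaining sample being assumed to vary like the other types. Without GIST 2 the mitosis list was at -0.97, and CDC20 (-1.80) and TPX2 (-1.75) were not called.

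Leiomyosarcoma was set apart by the contractile genes of smooth muscle. The smooth muscle myosin MYH11 was higher by 8.04 ± 0.73, the actin-binding LMOD1 by 7.15 ± 0.59, the myosin kinase MYLK by 5.95 ± 0.54, the enteric actin ACTG2 by 5.90 ± 0.45, calponin CNN1 by 5.82 ± 0.65 and desmin DES by 5.41 ± 0.72, with adjusted p of 2.86e-06 or lower. All 16 smooth muscle markers were called, also when adjusted over the list alone, and the list effect was 4.35 (adjusted p = 9.81e-37, and adjusted p = 0.00163 with an estimated correlation). The growth factor receptor PDGFRA was at -3.43 ± 0.63, the gelatinase MMP2 at -3.26 ± 0.48 and the long noncoding RNA MEG3 at -2.74 ± 0.68. Of 26 DNA replication genes, 5 rose, RFC4 at 1.52 and MCM2 at 1.34 among them, and the count was the same adjusted over the list alone (list effect 0.57, adjusted p = 4.92e-07, but adjusted p = 0.356 with an estimated correlation). In all, 337 genes were called higher and 182 lower. With all probe sets of a gene averaged, DES was at 2.56 and PDGFRA at -1.44, both still called.

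**Figure D3:**
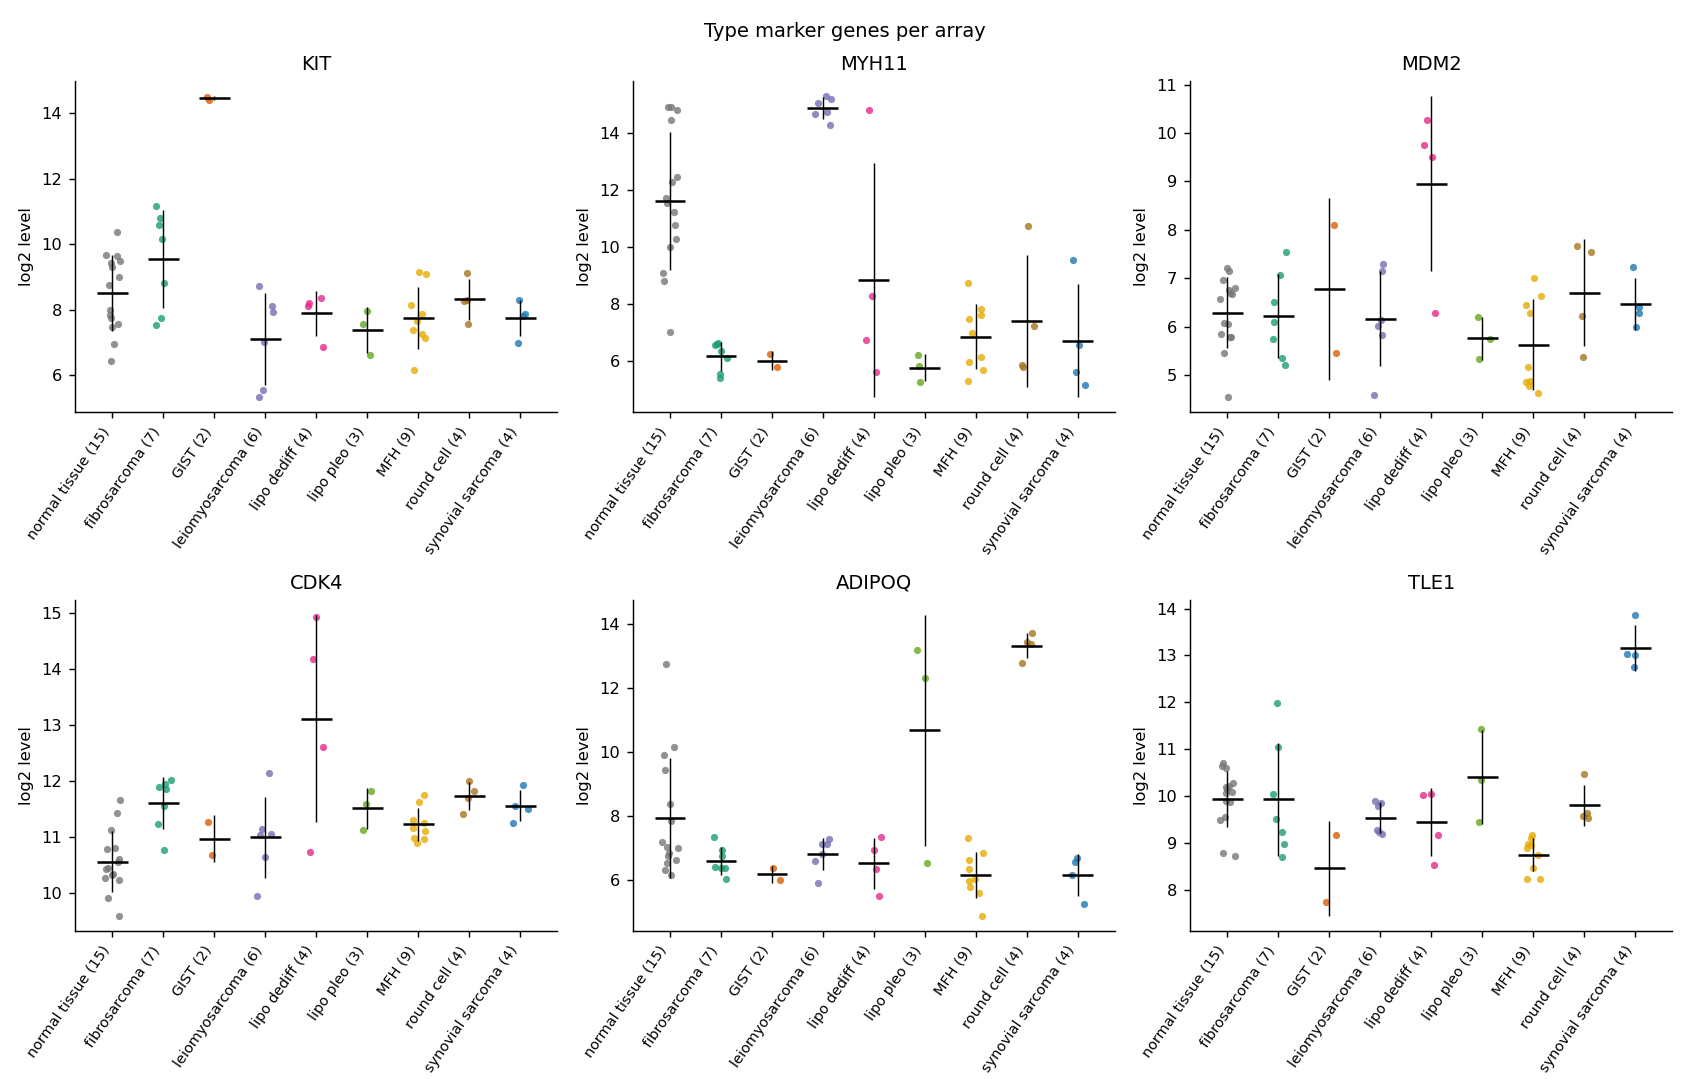
Log2 levels of 6 genes on each array (points), by group with the number of arrays, with the group mean (horizontal bar) and 1 SD on each side (vertical line). KIT averaged 14.46 in GIST and 9.55 in fibrosarcoma, the next highest type, and TLE1 averaged 13.16 in synovial sarcoma, where the means of the other types were 10.40 or lower.

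Genes of the chromosome 12 region q13-15 were higher in lipo dediff. MDM2, the ubiquitin ligase of p53, was higher by 2.70 ± 0.55 (adjusted p = 0.0118), the solute carrier SLC35E3 by 2.35 ± 0.39 (adjusted p = 0.00154), TSPAN31 by 2.31 (adjusted p = 0.0013) and the cell cycle kinase CDK4 by 1.74 ± 0.37 (adjusted p = 0.0133). HMGA2 from the same region was at 0.54 ± 0.66 (adjusted p = 0.745). Of 16 genes of the 12q13-15 list, 7 were called higher, and 10 when adjusted over the list alone, for a list effect of 1.37 (adjusted p = 1.81e-17, and adjusted p = 0.0037 with an estimated correlation). The largest rises of all were in matrix genes, COMP (4.03 ± 1.01, adjusted p = 0.0436), COL14A1 (3.59 ± 0.78) and OMD (3.36 ± 0.74). PRAME, a cancer-testis antigen, was at -2.46 ± 0.55, the chromatin ATPase ATAD2 at -2.41 ± 0.36 and COQ4, of coenzyme Q synthesis, at -2.27 ± 0.39.

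The 4 lipo dediff samples were unlike each other, and leaving out single arrays ended several of these calls. The 3' to 5' ratio was 0.83 ± 0.40 (SD, n = 4). Lipo dediff 2 had a 12q13-15 score of 8.59 against 10.44 to 11.02 in the other 3, and a smooth muscle score of 13.19, within the leiomyosarcoma range of 13.08 to 13.83. In all, 25 genes were called higher and 48 lower, or 34.2% higher. With arrays centred on their medians the share was 21.7% (20 and 72), where the median of all genes shifted to -0.11. Leaving out replicate 1, 2, 3 or 4 gave 48, 147, 111 and 25 called genes. The split turned to 29 higher and 19 lower (60.4% higher) without replicate 1 and was 19 and 92 (17.1% higher) without replicate 3. The calls of MDM2 (2.26, adjusted p = 0.121), CDK4 (1.14, adjusted p = 0.164), COMP (3.37), OMD (2.27) and PRAME (-2.29) were lost without replicate 4. MDM2 (2.52) and COL14A1 (3.61) were not called without replicate 1, nor were CDK4 (1.39), COMP (3.22) and COL14A1 (3.31) without replicate 3. Over its alternatives the adjusted p of MDM2 ran from 0.000209 to 0.131 and that of CDK4 from 2.83e-06 to 0.164. The smooth muscle list was at 0.85 (adjusted p = 0.00155, with no member of 16 called, and adjusted p = 0.499 with an estimated correlation) and at -0.09 without replicate 2 and 1.67 without replicate 1. The mitosis list was at -0.78 with 1 of 32 members called lower, or 4 adjusted over the list alone (adjusted p = 6.08e-09, but adjusted p = 0.449 with an estimated correlation). It was at -0.25 and not past the threshold without replicate 2, and at -1.17 without replicate 3.

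**Figure D4:**
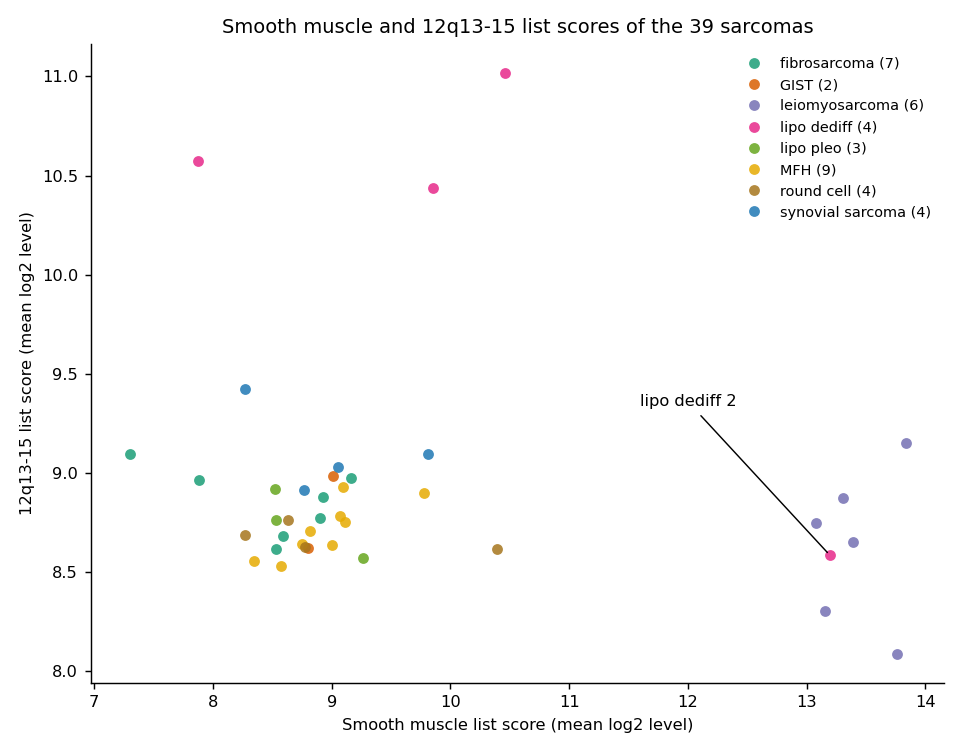
Smooth muscle list score against 12q13-15 list score (mean log2 level of the members) for the 39 sarcomas, each point an array, coloured by type. Of the 4 lipo dediff arrays, 3 lie above 10 on the 12q13-15 score, and lipo dediff 2 lies at 8.59 among the leiomyosarcomas.

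Fat cell genes were higher in lipo pleo. The retinol carrier RBP4 was higher by 5.20 ± 0.85 (adjusted p = 0.00119), lipoprotein lipase LPL by 3.78 ± 0.53 (adjusted p = 0.000189) and glycerol-3-phosphate dehydrogenase GPD1 by 3.57 ± 0.63 (adjusted p = 0.0023). The fatty acid carrier FABP4 was at 3.18 ± 1.22 and not called (adjusted p = 0.224). Of 14 fat cell markers, 9 were called, and 13 when adjusted over the list alone, for a list effect of 2.54 (adjusted p = 1.12e-21, and adjusted p = 0.00316 with an estimated correlation). The fat cell score was 10.94 and 11.28 in 2 of the samples and 7.39 in lipo pleo 3, without which the list effect was 3.84, GPD1 stood at 5.85 and FABP4 at 5.37. The skeletal muscle list was at 0.77 with 0 of 12 members called, also adjusted over the list alone (adjusted p = 0.0395, but adjusted p = 0.673 with an estimated correlation). Its score was 9.77 in lipo pleo 2 and 6.00 and 6.07 in the other samples, and without lipo pleo 2 the list effect was -0.59. Genes of hypoxia and glycolysis had a list effect of 1.10 with 2 of 23 called higher, or 10 adjusted over the list alone, and ANGPTL4 at 3.24 (adjusted p = 1.05e-11, but adjusted p = 0.0798 with an estimated correlation). The integrin ITGA7 was at 3.99 ± 0.94 and FCGBP at 3.56 ± 0.80, while EVC was at -2.65 ± 0.58, ATP2A3 at -2.38 ± 0.59 and FNDC3A at -1.67 ± 0.38. In all, 50 genes were called higher and 17 lower. Of the 8 genes named by size only LPL was called under every alternative but the stricter limit, and without replicate 1 or 2 only 10 and 23 genes were called. With all 54 arrays in the fit, 7 genes were called. The calls of RBP4 (4.07), FNDC3A (-0.91), GPD1 (2.52), FCGBP (3.14) and ANGPTL4 (3.25) were lost without replicate 1, those of GPD1 (2.36) and FCGBP (2.86) without replicate 2, and that of ANGPTL4 (2.87) without replicate 3. FABP4 was at 2.06 without replicate 1 and 2.11 without replicate 2. Leaving out any single replicate ended the calls of ITGA7 (3.77 to 4.13), ATP2A3 (-2.47 to -2.22) and EVC (-2.83 to -2.55).

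The round cell samples also had high fat cell genes. CTAG2, a cancer-testis antigen, was higher by 7.20 ± 0.78, the tachykinin precursor TAC1 by 6.82 ± 0.77, the fat cell hormone ADIPOQ by 6.31 ± 0.55, the pattern recognition protein PTX3 by 5.64 ± 0.44 and GPD1 by 5.60 ± 0.55, with adjusted p of 1.22e-07 or lower. Of 14 fat cell markers, 10 were called, and 11 when adjusted over the list alone, for a list effect of 3.13 (adjusted p = 2.72e-15, and adjusted p = 0.0199 with an estimated correlation). LPL was at 5.14 and FABP4 at 5.40. Of 12 markers of myxoid liposarcoma, 6 were called higher and 1 lower, or 7 and 1 adjusted over the list alone, for a list effect of 1.75 (adjusted p = 0.000806). The call was lost at adjusted p = 0.0798 with an estimated correlation and at 0.158 with the stricter filter, the highest of its alternatives. The stress gene DDIT3 was at 0.12 ± 0.24 (adjusted p = 0.802) and CD99 at -0.77 ± 0.29 (adjusted p = 0.0827), while MYOG was too dim to be tested. CLU was at -5.50 ± 1.05, ALDH1A3 at -4.09 ± 1.13 and NR2F1 at -3.91 ± 0.61. Most round cell levels of these genes lay near the floor of the scale, so the sizes are uncertain. Over the alternatives they ran from -6.36 to -4.16, from -5.11 to -3.02 and from -5.13 to -2.77. In all, 375 genes were called higher and 387 lower, or 414 and 324 with the scaling as deposited. Without round cell 2 the split was 302 and 209. Without round cell 3 the count was 436, and ALDH1A3 lost its call without round cell 2 (-4.06, adjusted p = 0.0525) or 3 (-4.04, adjusted p = 0.0582). The 3' to 5' ratio was highest in this type, at 1.05 ± 0.38 (SD, n = 4), and 331 genes were called with that ratio as a covariate, an alternative chosen after seeing the data.

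Synovial sarcoma had high TLE1, a transcriptional corepressor, at 3.69 ± 0.37 (adjusted p = 3.74e-08) above the other types. The Wnt inhibitor WIF1 was higher by 6.66 ± 0.81, TMEM30B by 5.36 ± 0.50, the homeobox gene MEOX2 by 5.30 ± 0.85, the BMP and Wnt modulator SOSTDC1 by 5.25 ± 0.74 and the cartilage collagen COL9A3 by 5.16 ± 0.78. The cancer-testis gene SSX1 was at 2.27 ± 0.76 and just short of the threshold (adjusted p = 0.0507, from 0.00865 to 0.382 over its alternatives). Of 13 synovial sarcoma markers, 8 were called higher, and 11 when adjusted over the list alone, among them FGFR3 at 4.14, PRAME at 3.97 and FZD10 at 3.66, for a list effect of 2.36 (adjusted p = 1.64e-11, and adjusted p = 0.00163 with an estimated correlation). Macrophage and interferon genes were low. Of 14 macrophage markers, 6 were called lower, and all 14 adjusted over the list alone, AIF1 at -2.83 and C1QB at -2.50 among them, for a list effect of -1.91 (adjusted p = 1.19e-08, but adjusted p = 0.372 with an estimated correlation). Of 20 interferon response genes, 8 were called lower, or 12 adjusted over the list alone, GBP1 at -2.67 and IFI27 at -2.43 among them, for a list effect of -1.26 (adjusted p = 4.52e-07, but adjusted p = 0.372 with an estimated correlation). PLAAT3 was at -3.70 ± 0.62, DPT at -3.44 ± 0.99 and PLA2G2A at -3.19 ± 0.98. In all, 354 genes were called higher and 336 lower, or 371 and 238 with the scaling as deposited and 257 and 335 with arrays centred on their medians. The count was 458, 349 and 372 without replicate 1, 3 or 4. PLA2G2A was not called without any single replicate (-3.39 to -2.95), and DPT not without replicate 2, 3 or 4 (-3.09, -3.22 and -3.62). Of the macrophage and interferon genes named, AIF1 (-2.29), C1QB (-2.19), GBP1 (-2.35) and IFI27 (-2.16) lost their calls without replicate 3, AIF1 (-2.64) and C1QB (-2.49) without replicate 4, and IFI27 (-2.27) without replicate 2. With all probe sets of a gene averaged, SSX1 was at 0.90 and MEOX2 at 2.62.

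The MFH samples had higher interferon, macrophage and matrix genes than the mean of the other types. The macrophage score was higher still in lipo pleo (11.32, against 11.13 in MFH) and the matrix score in lipo dediff (12.86, against 12.66), differences that were not tested. The calcium-binding S100A4 was higher by 3.43 ± 0.54, the hyaluronan-binding TNFAIP6 by 3.37 ± 0.50, the semaphorin SEMA3C by 3.08 ± 0.58, the matrix gene FBLN2 by 2.89 ± 0.67 and S100A6 by 2.79 ± 0.49, with adjusted p of 0.00541 or lower. Of 20 interferon response genes, 7 were called higher, or 10 adjusted over the list alone, GBP1 at 2.12 and IFI27 at 2.10 among them, for a list effect of 1.07 (adjusted p = 9.04e-10, but adjusted p = 0.329 with an estimated correlation). Of 14 macrophage markers, 5 were called higher, or 11 adjusted over the list alone, CD163 at 1.94 and MSR1 at 1.74 among them, for a list effect of 1.31 (adjusted p = 5.81e-08, but adjusted p = 0.372 with an estimated correlation). Of 23 matrix genes, 7 were called higher, or 9 adjusted over the list alone, DCN and LUM at 2.62 among them, for a list effect of 0.80 (adjusted p = 0.000146, but adjusted p = 0.387 with an estimated correlation). Of 32 mitosis genes, 11 were called higher, also adjusted over the list alone, AURKA at 1.65 and CDC20 at 1.53 among them, for a list effect of 0.85 (adjusted p = 3.39e-14, but adjusted p = 0.356 with an estimated correlation). The mitosis score was nearly the same in fibrosarcoma (9.52, against 9.53 in MFH) and was lowest in GIST (7.31). The basement membrane collagen COL4A5 was at -2.74 ± 0.47, the imprinted gene PEG3 at -2.60 ± 0.39 and the Wnt antagonist SFRP1 at -2.54 ± 0.62. In all, 265 genes were called higher and 143 lower, or 65.0% higher, and 51.6% with the scaling as deposited (248 and 233). LUM was not called without replicate 1, 3, 4, 5, 8 or 9 (2.46 to 2.54), nor were AURKA (0.75) and MSR1 (0.86) with all probe sets of a gene averaged.

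In the fibrosarcomas the neurofilament gene NEFM was higher than in the other types by 2.97 ± 0.50 (adjusted p = 0.00118), the cartilage collagen COL2A1 by 2.75 ± 0.62, the neurofilament NEFL by 2.74 ± 0.71, and the homeobox genes PRRX2 by 2.68 ± 0.49 and HOXB13 by 2.63 ± 0.52. COX7A1, a subunit of muscle cytochrome oxidase, was at -3.19 ± 0.61, RARRES2 at -2.66 ± 0.59 and PLAAT3 at -2.50 ± 0.50. Of 32 mitosis genes, 5 were called higher, or 11 adjusted over the list alone, DLGAP5 at 1.54 and CCNB2 at 1.26 among them, for a list effect of 0.85 (adjusted p = 1.26e-18, but adjusted p = 0.278 with an estimated correlation). The mitosis score averaged 9.52 in the fibrosarcomas and 9.53 in MFH. Of 16 smooth muscle markers, 1 was called lower, MYLK at -2.17, or 9 adjusted over the list alone, for a list effect of -1.32 (adjusted p = 6.03e-10, but adjusted p = 0.240 with an estimated correlation). In all, 55 genes were called higher and 43 lower. Leaving out replicate 3, 4 or 5 gave 48, 60 and 58 called genes. COL2A1 lost its call without replicate 3 (2.37), 4 (1.98), 5 (2.60) or 6 (2.47), NEFL without replicate 3 (2.20), 4 (2.28), 5 (2.71), 6 (2.62) or 7 (2.81), or without lipo dediff 2 (2.67), and RARRES2 without replicate 3 (-2.31) or 5 (-2.32). DLGAP5 (1.26) and CCNB2 (1.04) were not called without replicate 5, nor MYLK without replicate 3 (-1.72) or 6 (-1.92). With the 3' to 5' ratio as a covariate, chosen after seeing the data, 63 genes were called, and COL2A1 (2.55), NEFL (2.89), RARRES2 (-2.28), CCNB2 (1.19) and MYLK (-1.92) were not. That ratio was lowest in this type, at 0.19 ± 0.08 (SD, n = 7).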

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

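The tests of an exchange and of weak hybridisation for lipo dediff 2, the fits without it, and the tests of whether a list's shift differed between types were chosen after the values were seen.

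Of the 10 gene lists past the threshold against normal tissue, 6 had shifts that differed between sarcoma types. In 2 of these the type means lay on both sides of the normal mean. The test compares types with each other, and no single type was tested against normal tissue. The collagen and matrix list was shifted by 2.47 in lipo dediff and by -0.18 in GIST, and the shifts differed between the 8 types (permutation test, adjusted p = 0.00332 over 10 lists). The GIST value is near 0 beside the normal SD of 1.38, so it does not show a fall. The fat cell list was shifted by 1.74 in round cell and by -1.66 in synovial sarcoma (permutation test, adjusted p = 0.0003). The mitosis, DNA replication, DNA repair and matrix remodelling lists were shifted upward in all 8 types, by amounts that differed between them (permutation tests, adjusted p = 0.0015, 0.00125, 0.00332 and 0.0151). For the skeletal muscle, lymphocyte, red blood cell and epithelial lists the test of a difference did not pass the threshold (adjusted p from 0.184 to 0.943).

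Single arrays stood apart from their type in 5 of 65 values tested, where chance gives about 5 percent. DES was at 9.17 in leiomyosarcoma 5, where the other 5 samples lay between 12.68 and 13.52. NR2F1 was at 7.47 in round cell 3, against 4.29 to 4.62 in the other 3. In round cell 4 CLU was at 8.24 and ALDH1A3 at 5.00, against 4.63 to 4.97 and 4.58 to 4.65. The ALDH1A3 levels all lie near the floor of the scale, so its difference says little about that array. SLC35E3 was at 7.68 in lipo dediff 2, against 11.08 to 11.51 in the other 3 samples of that type. MFH 5, not among these 5, had a skeletal muscle score of 11.18, where the other MFH samples lay between 6.04 and 6.96. The cause was not tested.

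Lipo dediff 2 differed from the other 3 lipo dediff samples in more than SLC35E3, with MDM2 at 6.28, CDK4 at 10.7, MYH11 at 14.8 and a smooth muscle score of 13.19, where the highest of the 32 other arrays that are not leiomyosarcoma was 10.46. An exchange with a leiomyosarcoma sample is argued against, because 0 of the 6 leiomyosarcoma arrays had a smooth muscle score within the range of the other types, and weak hybridisation because the CreX control was at 14.3, below the mean of 15.9 of the other 3 by more than their SD of 1.17. Normal smooth muscle in the specimen stays open as a possible explanation. Its mitosis score of 6.53 was the lowest of the 39 sarcomas, and lay a little below the 6.83 to 7.87 of the 4 normal organs rich in smooth muscle. A wrong label not involving these leiomyosarcomas and a tumor with smooth muscle differentiation were not tested, and without this array 147 genes were called (50 higher and 97 lower, 59 of them also called with all 4 arrays), among them 12 of the 16 genes of the 12q13-15 list.

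The fat cell genes of the round cell type are the other pattern weighed here. Fat tissue mixed into the specimens would bring all abundant transcripts of mature fat cells, and it is argued against by the mean log2 fold change of ADH1B and LEP, which was -0.78 (SE 0.50). ADH1B averaged 5.65 in round cell and LEP 5.23, where the normal connective tissue sample was at 11.9 and 9.75. Other mature fat cell genes were mixed: ADIPOQ (6.31), GPD1 (5.60) and PLIN1 (4.17) rose, while CIDEC (0.58) and LIPE (0.49) were not called. These fold changes come from a fit without the filter, because LEP was too dim to pass it. The argument thus rests on ADH1B and LEP. Weak hybridisation of round cell 2 is argued against too, since without that array the list effect was 3.15 (adjusted p = 8.6e-16, from 3.01e-17 to 0.0199 over its alternatives). A fat cell program of the tumor cells themselves may therefore be a candidate explanation, as a hypothesis that was not tested separately.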

How the results depend on the processing

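The 3' to 5' ratio and the CreX control as covariates, the 5 normal tissues with little epithelium, and the fits without the 3 arrays with the highest CreX control or without lipo dediff 2 were chosen after the data were seen. Of 13751 values of 509 single genes under the alternatives, 12760 kept their direction and side of the threshold, 684 fell short of it, 294 newly passed it and 13 reversed. For the 93 lists past the threshold the counts were 2004, 280, 0 and 4 of 2288. Lists not past it were left out of this count after a first look, in which many of them, near 0 and with no call, changed sign.

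For the counts that moved by over 1.5 times, fewer or more genes pass a changed threshold or filter by construction, and for the others the cause was not tested. In sarcoma against normal tissue, a pseudocount of 64 gave 487 higher and 471 lower genes, no fold minimum 2054 and 1829, the stricter filter 285 lower, and the 5 normal tissues with little epithelium 1163 higher. In fibrosarcoma the stricter filter gave 65 genes. Array weights gave 936 genes in GIST, 10 in lipo dediff, 252 in lipo pleo and 1077 in synovial sarcoma. No fold minimum gave 825 in leiomyosarcoma and 823 in MFH. An adjusted p below 0.01 gave 32 in fibrosarcoma, 191 in GIST, 307 in leiomyosarcoma, 9 in lipo dediff, 19 in lipo pleo, 206 in MFH, 383 in round cell and 281 in synovial sarcoma. With all 54 arrays in the fit the counts were 63 in fibrosarcoma, 231 in GIST, 28 in lipo dediff, 7 in lipo pleo, 499 in round cell and 387 in synovial sarcoma. The ratio covariate gave 63 in fibrosarcoma and 331 in round cell, and leaving out the 3 arrays with high CreX gave 32 in lipo dediff. Lists past the threshold with an estimated correlation numbered 4 against normal tissue and 6 between types, and with fry 42 between types.

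Leaving out single arrays gave 641 to 906 higher and 646 to 787 lower genes against normal tissue, and 9 to 14 lists. Between types it gave 48 to 141 genes in fibrosarcoma, 131 to 464 in GIST, 383 to 532 in leiomyosarcoma, 25 to 147 in lipo dediff, 10 to 66 in lipo pleo, 342 to 415 in MFH, 436 to 764 in round cell, and 349 to 732 in synovial sarcoma.

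Values that reversed were small or rested on a single array, and the cause was not tested. CAV1 against normal tissue was at -0.47 with the 8 tissues rich in mesenchyme or muscle. With the 5 tissues C1QB was at -0.28, ISG15 at -0.34, VEGFA at 0.050 and FOS at 0.12. Without single arrays, ERBB2 in GIST ran from -3.17 to 0.20. In lipo dediff HMGA2 ran from -0.47 to 1.00, CNN1 from -0.0016 to 2.95, and the lists of lymphocytes from -0.37 to 1.04, smooth muscle from -0.085 to 1.67 and matrix remodelling from -0.01 to 0.71. In lipo pleo TNNC2 ran from -0.13 to 3.14, MYL1 from -1.04 to 2.68, MMP13 from -0.13 to 3.89 and the skeletal muscle list from -0.59 to 1.48. In round cell SSX1 ran from -0.067 to 1.5 and MAGEA1 from -0.082 to 1.43.

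Replicate numbers only name samples here. Deviations of samples with the same number had a mean correlation of 0.0108 over 99 pairs (from -0.195 to 0.159), and those with different numbers -0.0018 over 548 pairs. With the number as a block the counts were 75 in fibrosarcoma, 374 in GIST, 534 in leiomyosarcoma, 49 in lipo dediff, 67 in lipo pleo, 375 in MFH, 697 in round cell, 610 in synovial sarcoma, and 74 lists. Dim genes are limited by signal over background, since the median intensity per array was only 141.4 to 279.2.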

Other observations

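The test of an exchange of the colon and small intestine labels, and the genes FABP6 and DEFA5, were chosen after the values were seen.

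PRAME and CTAG2, cancer-testis antigens mostly silent outside the testis, were called higher in round cell and in synovial sarcoma. PRAME was at 4.07 in round cell and 3.97 in synovial sarcoma, and CTAG2 at 7.20 and 3.27. In synovial sarcoma the call of CTAG2 was lost without replicate 2 (2.44), 3 (2.86) or 4 (2.85). The list of pluripotency and cancer-testis genes had an effect of 1.87 in round cell with 2 of 7 members called, also adjusted over the list alone (adjusted p = 0.0107, but adjusted p = 0.372 with an estimated correlation). Without round cell 3 it was at 1.42 and not past the threshold. In synovial sarcoma the list effect was 1.78 with 3 of 7 members called, or 4 adjusted over the list alone (adjusted p = 0.00123, but adjusted p = 0.329 with an estimated correlation).

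Synovial sarcoma had an epithelial list effect of 0.78 against the other types, with 1 of 9 members called, the protease inhibitor SPINT2 at 2.59, or 2 adjusted over the list alone (adjusted p = 0.0498, but adjusted p = 0.455 with an estimated correlation). CDH1 was at 2.24 and not called (adjusted p = 0.0536). The epithelial scores were 7.75, 7.95, 6.12 and 6.34 in the 4 samples, and the call was lost without replicate 1 (0.67) or 2 (0.61). In lipo pleo the macrophage list was at 1.53, with 0 of 14 members called and 6 called higher when adjusted over the list alone (adjusted p = 7.39e-08, but adjusted p = 0.372 with an estimated correlation).

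The array labelled colon had high levels of small intestine genes, with the brush border sucrase SI at 13.3, the apolipoprotein APOA4 at 12.4, the ileal bile acid carrier FABP6 at 15.5 and the Paneth cell defensin DEFA5 at 15.4. On the array labelled small intestine they were at 12.7, 8.89, 4.66 and 15.4. Small intestine tissue under the colon label may be a candidate explanation, because the large bowel gene CEACAM7 was at 6.51, not above the mean of 6.95 (SD 0.755) of the 13 other normal tissues. However, the colon markers MUC2 and CEACAM5 were highest on this array. CA1, the other colon marker fixed beforehand, was at 7.08 there, rank 15 of the 15 normal tissues. An exchange of the 2 labels is argued against, since CA1, CA4, MS4A12 and AQP8 averaged 6.86 on the array labelled small intestine, below the mean of 7.58 (SD 0.752) of those 13 tissues. No biological explanation was tested, and without the array labelled colon 806 genes were called higher and 727 lower in the sarcomas.

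Other splits of the samples into groups of the same sizes gave fewer called genes in every comparison with at least 3 samples a group. All type labels were shuffled together, so the other splits held the real differences between types in their spread, which lowers their counts. The splits therefore show that the labels carry information, but cannot exclude chance for the count of any single type. In each, 1 of 100 splits, the real one, gave as many. Against normal tissue the real split gave 1495 genes and the highest other 100. The real counts and the highest others were 98 and 13 in fibrosarcoma, 519 and 12 in leiomyosarcoma, 73 and 14 in lipo dediff, 67 and 27 in lipo pleo, 408 and 2 in MFH, 762 and 23 in round cell, and 690 and 168 in synovial sarcoma.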
